A study of Cucumis sativus with 11 samples.

How the data were processed

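RNA of cucumber leaves was measured in 11 libraries of 4 groups, with 3 control, 3 salt, 2 silicon and 3 salt plus silicon libraries. Per the labels' protocols, seedlings of the cultivar JinYou 1 grew in nutrient solution, salt was given as 75 mM sodium chloride and silicon as 0.3 mM sodium silicate, and young, fully expanded leaves were taken after 3 days, with 3 leaves combined into each biological replicate. Per the labels' protocols, poly(A) RNA was fragmented and made into libraries that do not keep strand, so reads of a gene and of a gene on the opposite strand at the same place are not told apart. Per the submitters' processing notes, TopHat2 was among the tools. Its version and settings, the program that counted reads, the genome build and the annotation are not given in the sources used here.

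The authors deposited 1 value per gene and library, in RPKM (reads scaled by gene length and by the mapped reads of the library), as the deposited tables are named. Each table listed the same 20165 gene IDs, and 127 of them were at 0 in all libraries. No counts were in the files used here, so absolute depth is unknown and no counting interval or detection floor was computed. Values of genes under 0.2 RPKM gave an estimate of the libraries' relative depth, since the smallest step is worth 1 read. Only ratios to control 1 that were close to 1 were kept, so a large difference in depth could not have shown. The estimate lay between 0.884 (salt 2) and 1.148 (salt plus silicon 3) of control 1. The steps of 1 read did not keep an exact ratio between libraries, so whole reads were not recovered and no count test was run. An exact 0 can be a failed estimate, and a gene without a value above 0 is described only as listed at 0. No pair of libraries shared more than 1 identical value above 0, so each was counted as its own sample.

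Values were used as deposited and transformed to log2(RPKM + 1). Genes with 1 RPKM or more in at least 2 libraries were tested, 17408 in number. Group means of all 11 libraries were fitted with limma 3.58.1 in R 4.3.3, with a mean-variance trend and no block, leaving 7 residual degrees of freedom. All tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Adjusted p-values and standard errors (SE) below come from this fit, a called gene is one past that threshold, and log2 fold changes are on the log2(RPKM + 1) scale, which understates changes of low genes. An exact permutation test of 3 libraries against 3 cannot give a two-sided p below 0.10. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.

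The test was tried on simulated data with 200 changed genes among 17408, with noise that kept the correlation between genes. Over 20 simulations it recovered 19.55% of 2-fold and 60.45% of 4-fold changes for salt against control, 10.0% and 47.05% for silicon against control, and 14.3% and 55.5% for salt plus silicon against salt. The mean number of false calls was 83.3, 5.3 and 1.9, with a median of 0 in each. In 100 simulations of the same kind with no effect at all, the median number of calls was 0 in each comparison, but single simulations reached 752 for salt against control and 862 for silicon against control, and up to 6485 in the others. As many calls as observed came up in 0 of 100 for salt against control and for silicon against control. It was 1 of 100 for salt plus silicon against control and 1 for salt plus silicon against salt. It was 3 for salt plus silicon against silicon and 3 for the interaction. Simulated noise was continuous and alike in all libraries, so a gene at exact 0 in some groups alone could not arise. The 3 genes called for salt plus silicon against salt had such zeros, so that 1 of 100 does not bear on them.

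Groups, tests, the rule for named genes and most alternatives were fixed before the data were examined. The alternatives were a smaller pseudocount of 0.1, no filter and a stricter filter of 5 RPKM, median-of-ratios scaling, quantile normalization, a replicate block, robust moderation, a fit of the compared groups alone, and leaving out each library. Counting calls without genes that were listed at 0 in a whole compared group was added after seeing the data. The rule asked, where IDs could not be paired with gene names, for 2 IDs that rose and 2 that fell in each comparison, by log2 fold change among calls of 2-fold or more without overlap between the libraries compared. For the interaction, which takes in all 4 groups, overlap was not considered. After values had been seen, a condition was added that no library of the compared groups be at 0. The 3 genes called for salt plus silicon against salt do not meet it and are named because they are few. The files give IDs without names, and 0 of the 20165 IDs matched the 23999 genes of the reference table, so IDs are given as the files give them. For that reason 41 gene lists fixed beforehand by product name could not be tested.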

Results

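Leaf RNA was profiled in cucumber plants grown with or without 75 mM sodium chloride and with or without 0.3 mM silicon, to ask how silicon changes gene expression in salt-stressed leaves. There were 3 control, 3 salt, 2 silicon and 3 salt plus silicon libraries, each from 3 combined leaves. Depth was estimated only relative to control 1, between 0.884 and 1.148, by a method that could not show a large difference. Between 1711 and 2397 of the 20165 listed genes were at 0 in a library. Csa5G609710, the gene with the highest value, held 8.69% ± 1.41 (SD, n = 3) of the summed RPKM in control, 6.24% ± 0.486 (n = 3) in salt, 4.64% ± 0.612 (n = 2) in silicon and 6.16% ± 1.60 (n = 3) in salt plus silicon libraries, and its level did not pass the test with salt (limma, adjusted p = 0.215) or silicon (adjusted p = 0.121). The median log2 change of all tested genes was 0.11 for salt, 0.18 for silicon and 0.14 for salt plus silicon, each against control, and -0.15 for the interaction. These shifts moved the balance of higher and lower genes, so the balance after other scalings stands beside each count. Within groups, the SD of log2 differences between libraries ran from 0.874 to 0.986 in control, 0.740 to 0.960 in salt and 0.728 to 0.799 in salt plus silicon, and was 0.845 between the silicon libraries. On the first principal component (31.6% of variance) the silicon libraries lay at -98.7 and -86.9, control 1 at -45.4, and the other libraries between -3.71 and 47.2.

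With salt alone, 1587 of 17408 tested genes differed from control, 1064 higher and 523 lower. Csa1G062380 rose from 4.27 ± 1.27 RPKM (SD, n = 3) to 262 ± 139 (n = 3), a log2 fold change of 5.48 ± 0.60 (SE, limma adjusted p = 0.00223). Csa3G818250 rose from 6.57 ± 2.63 to 142 ± 48.5 RPKM, a log2 fold change of 4.26 ± 0.35 (adjusted p = 0.00144). Csa6G423390 fell from 180 ± 30.02 to 6.53 ± 2.40 RPKM, a log2 fold change of -4.63 ± 0.60 (adjusted p = 0.00431), and Csa4G312880 fell from 36.4 ± 16.01 to 1.16 ± 0.832 RPKM, a log2 fold change of -4.10 ± 0.47 (adjusted p = 0.00249). The median log2 change was 1.01 in the 1064 higher genes and -1.35 in the 523 lower genes, against 0.11 in all genes. Since both sets were chosen by this change, their distance from all genes is built in. Of the calls, 543 were higher and 401 lower by 2-fold or more, which turned to 375 and 602 after median-of-ratios scaling and to 406 and 497 after quantile normalization. Most calls were higher as deposited, but the balance turned to 737 higher and 840 lower after median-of-ratios scaling and was 805 and 644 after quantile normalization. The count fell to 196 when the 6 libraries were fitted alone, and to 452 without control 2, 1048 without control 3, 646 without salt 1 and 593 without salt 3.

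In the 2 libraries with silicon alone, 1629 genes differed from control, 1459 higher and 170 lower. Csa2G010390 rose from 33.9 ± 48.3 RPKM (SD, n = 3) to 1675 ± 1083 (n = 2), a log2 fold change of 6.86 ± 1.25 (SE, limma adjusted p = 0.0129), with control libraries at 89.3, 11.6 and 0.871 RPKM. Csa7G037610 rose from 78.6 ± 74.9 to 3750 ± 370 RPKM, a log2 fold change of 6.36 ± 1.40 (adjusted p = 0.0235). Csa1G586900 fell from 8.19 ± 1.06 to 1.62 ± 1.29 RPKM, a log2 fold change of -1.90 ± 0.34 (adjusted p = 0.0125), and Csa6G512910 fell from 89.6 ± 7.23 to 26.2 ± 10.3 RPKM, a log2 fold change of -1.79 ± 0.32 (adjusted p = 0.0117). The median log2 change was 1.59 in the 1459 higher genes and -0.93 in the 170 lower genes, against 0.18 in all genes. Since both sets were chosen by this change, their distance from all genes is built in. The balance was 1033 higher and 375 lower after median-of-ratios scaling and 839 and 456 after quantile normalization. The count was 53 when the 5 libraries were fitted alone, 80 without silicon 1, 706 without silicon 2, 538 without control 2, 710 without control 3 and 2515 without control 1, and it was 1031 with a replicate block. Calls for all 4 named genes were lost in the fit of the 5 libraries alone, and that of Csa7G037610 also without either silicon library, control 2 or control 3. The calls for Csa2G010390 and Csa6G512910 were lost without silicon 1, and that for Csa1G586900 without silicon 2.

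**Figure D1:**
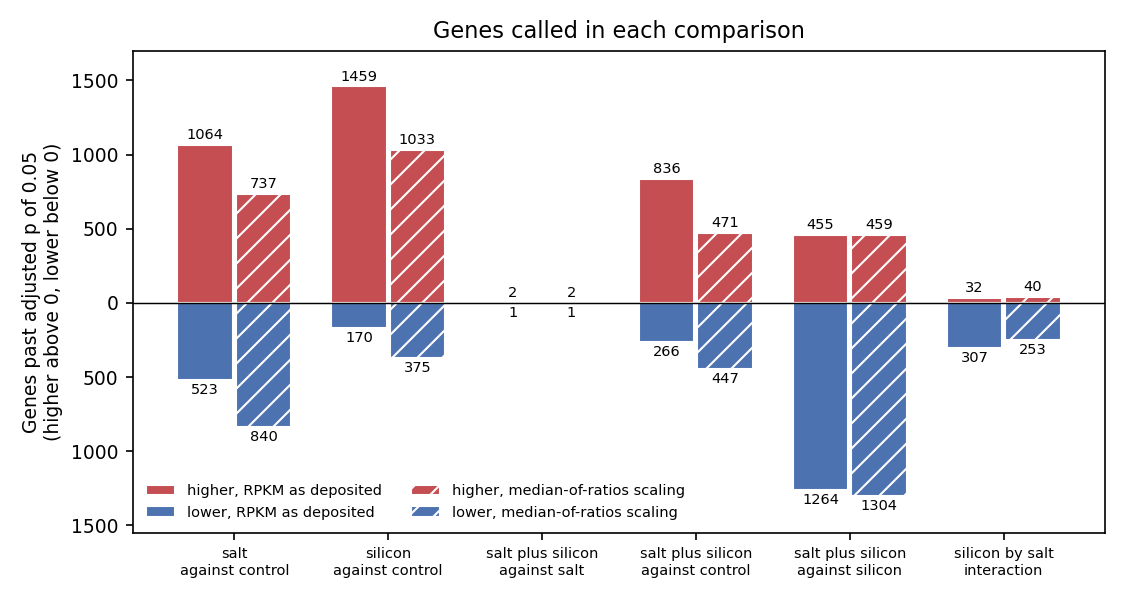
Number of genes past an adjusted p of 0.05 in each comparison, higher above 0 and lower below 0, with RPKM as deposited (plain bars) and after median-of-ratios scaling (hatched bars). Salt against control goes from 1064 higher and 523 lower to 737 and 840, and silicon against control from 1459 and 170 to 1033 and 375.

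Between salt plus silicon and salt libraries, 3 of 17408 genes differed. Csa1G050120 was listed at 0 in the salt libraries and at 37.9, 23.3 and 31.5 RPKM in the salt plus silicon libraries (limma adjusted p = 6.14e-06). Csa6G358140 was listed at 0 in the salt libraries and at 14.5, 7.77 and 8.64 RPKM with silicon added (adjusted p = 0.00048), a call lost under the stricter filter. Csa6G116670 was at 267, 328 and 156 RPKM in the salt libraries and listed at 0 in the salt plus silicon libraries (adjusted p = 8.62e-07). Each of them was listed at 0 in the 8 libraries outside the group that held values. Groups at 0 have no spread, which lowers the shared spread of these genes and their p-values. With the 6 libraries fitted alone, limma adjusted p was 0.001615 for Csa1G050120, 0.0239 for Csa6G358140 and 0.001019 for Csa6G116670. That fit, too, had a group at 0 for each gene. After median-of-ratios scaling and after quantile normalization, 2 genes were higher and 1 lower, as with the values as deposited. These 3 genes were all of the calls, so the count without them was 0. Among all 17408 tested genes, 489 had an unadjusted limma p under 0.05, where 870.4 would on average with no effect. Genes varied together, and the fit shared its spread with the control libraries, which varied more than the salt plus silicon libraries. A count under the average therefore does not show that silicon had no effect. For 11991 genes, 68.9% of those tested, the 95% interval of the change lay within 2-fold in either direction on the log2(RPKM + 1) scale. The count ran from 3 to 12 with 1 library left out, being 5 without control 2 or salt 1, 9 without salt 2 or salt 3, 7 without salt plus silicon 1, 12 without salt plus silicon 2 and 6 without salt plus silicon 3, and it was 10 when the 6 libraries were fitted alone.

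Of the 1587 salt-changed genes, 1172 (73.8%) had a salt plus silicon mean on the control side of the salt mean. Simulations in which silicon had no effect on salt-treated plants gave 63.0% ± 13.2 (SD), and 20 of 100 gave as large a share, so the share lay within the simulated spread. The median part of the salt change that was returned was 12.2%, against 8.21% ± 8.27 simulated. A division by direction, added after the values were seen, gave 66.5% on the control side for genes that rose with salt (61.5% ± 14.4 simulated, 34 of 100 as large) and 88.7% for genes that fell (64.6% ± 16.6, 3 of 100 as large). The median part returned was 7.22% for those that rose (6.98% ± 8.80 simulated, 46 of 100 as large) and 22.6% for those that fell (10.1% ± 11.4, 13 of 100 as large), and the difference between the directions was not tested. The 523 genes that fell with salt had a library median of 38.9 ± 0.919 RPKM in control, 12.8 ± 2.03 in salt and 16.8 ± 1.95 in salt plus silicon (SD, n = 3 each), and the 1064 that rose had 8.53 ± 0.894, 19.9 ± 0.681 and 18.7 ± 1.78.

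With salt plus silicon, 1102 genes differed from control, 836 higher and 266 lower. Csa3G818250 rose from 6.57 ± 2.63 RPKM (SD, n = 3) to 160 ± 47.2 (n = 3), a log2 fold change of 4.44 ± 0.35 (SE, limma adjusted p = 0.000699), and Csa3G604110 rose from 5.13 ± 0.618 to 130 ± 33.8 RPKM, a log2 fold change of 4.39 ± 0.35 (adjusted p = 0.000743). Csa6G497240 fell from 41.7 ± 14.8 to 1.83 ± 0.679 RPKM, a log2 fold change of -3.88 ± 0.34 (adjusted p = 0.000947). Csa6G423390 fell from 180 ± 30.02 to 16.3 ± 12.6 RPKM, a log2 fold change of -3.77 ± 0.60 (adjusted p = 0.0101), a call lost when the 6 libraries were fitted alone. The salt and the salt plus silicon comparison shared 660 higher and 229 lower calls, where independent lists would share 51.1 and 8.0, and none were opposite in direction. Across genes, which are not independent replicates, the log2 changes correlated at r = 0.818, against 0.474 ± 0.293 (SD) simulated with no effect, and their covariance of 0.453 was 0.349 above the simulated 0.104 ± 0.0881. Part of the excess in shared calls may come from the shared controls, of which there were too few to give each comparison 2 of its own. The balance of calls was 471 higher and 447 lower after median-of-ratios scaling and 492 and 342 after quantile normalization. The count was 475 when the 6 libraries were fitted alone, 727 with a replicate block, 304 without control 2, 602 without control 3, 326 without salt plus silicon 1, 438 without salt plus silicon 2 and 215 without salt plus silicon 3.

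**Figure D2:**
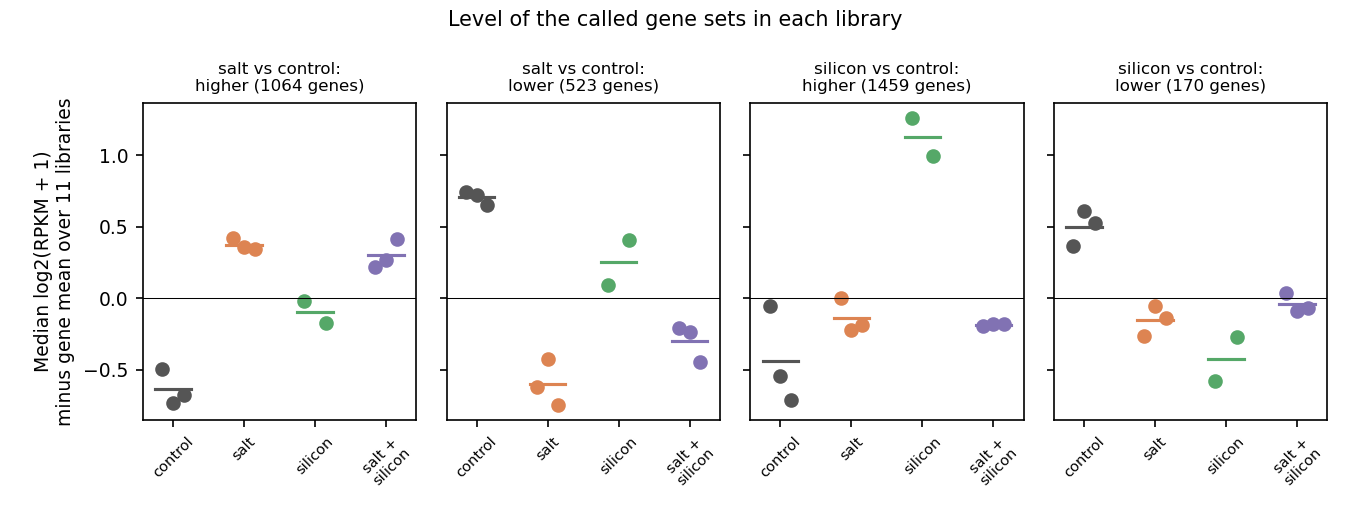
Median log2(RPKM + 1), relative to each gene's mean over 11 libraries, of genes called higher or lower with salt or silicon; points are libraries and lines group means. The 1459 silicon-higher genes stand at 1.26 and 1.00 in the silicon libraries and between -0.23 and 0.00 in salt and salt plus silicon libraries. They stand at -0.05 in control 1, -0.55 in control 2 and -0.71 in control 3. The number of genes in each set depends on scaling.

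Between salt plus silicon and silicon libraries, 1719 genes differed, 455 higher and 1264 lower with salt. Csa1G572420 rose from 0.753 ± 0.121 RPKM (SD, n = 2) to 42.2 ± 24.03 (n = 3), a log2 fold change of 4.49 ± 0.77 (SE, limma adjusted p = 0.00676), and Csa3G874380 rose from 3.36 ± 1.95 to 89.0 ± 35.8 RPKM, a log2 fold change of 4.37 ± 0.68 (adjusted p = 0.00452). Csa7G452230 fell from 1944 ± 1189 to 4.38 ± 1.61 RPKM, a log2 fold change of -8.40 ± 1.35 (adjusted p = 0.00521), and Csa2G010390 fell from 1675 ± 1083 to 4.70 ± 2.06 RPKM, a log2 fold change of -8.09 ± 1.25 (adjusted p = 0.00443). Of the 1264 lower genes, 854 were among those higher with silicon alone, where independent lists would share 105.9. Both comparisons rest on the same 2 silicon libraries with opposite sign, so part of this overlap may come from them. Across genes the log2 changes correlated at r = -0.714, within the spread of -0.562 ± 0.261 (SD) simulated with no effect, and their covariance was -0.639, against -0.149 ± 0.117 simulated. The comparison shares no library with salt against control, and the calls had 221 higher and 126 lower genes in common, where independent lists would share 27.8 and 38, with 21 opposite in direction. Across genes the log2 changes correlated at r = 0.342, against a simulated 0.00 ± 0.359 (SD) with no effect, and their covariance was 0.264, against -0.00414 ± 0.0840 simulated. After quantile normalization 916 genes were higher and 1167 lower, and after median-of-ratios scaling 459 and 1304. The count was 409 without silicon 1, 712 without silicon 2, 1039 without salt plus silicon 1 and 955 without salt plus silicon 3. Each of the 4 named calls was lost without silicon 1, and that of Csa1G572420 also without silicon 2.

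The interaction term of salt and silicon passed the test in 339 genes, 32 higher and 307 lower. Csa1G062380 rose with salt alone to 262 ± 139 RPKM (SD, n = 3) but stood at 78.7 ± 52.6 (n = 2) with silicon and 32.0 ± 17.2 (n = 3) with both, an interaction of -6.74 ± 0.90 on the log2 scale (SE, limma adjusted p = 0.0123). Csa6G486960 was at 2.45 ± 3.18 RPKM in control, 13.7 ± 14.5 in salt, 116 ± 49.6 in silicon and 1.63 ± 1.36 in salt plus silicon libraries, an interaction of -7.39 ± 1.30 (adjusted p = 0.0264). Csa3G646510 stood at 133 ± 42.9, 11.6 ± 5.08, 62.6 ± 14.2 and 32.0 ± 2.78 RPKM in the same order, an interaction of 2.50 ± 0.47 (adjusted p = 0.0338), and Csa1G423000 at 187 ± 39.3, 49.1 ± 25.04, 66.0 ± 24.9 and 91.2 ± 18.5 RPKM, an interaction of 2.49 ± 0.53 (adjusted p = 0.0484). Of the 307 lower genes, 301 were higher with silicon alone, an overlap that is partly built in, since the interaction contains silicon minus control with opposite sign. Across genes the 2 terms correlated at r = -0.901, within the spread of -0.714 ± 0.211 (SD) simulated with no effect, and their covariance was -0.829, against -0.257 ± 0.180 simulated. The 1459 silicon-higher genes had a median log2 change of 1.59 for silicon against control, -0.04 for salt plus silicon against salt and -1.64 for the interaction. These genes were picked for a high silicon minus control difference, so 1.59 is raised by that choice. The interaction contains that difference with opposite sign, so -1.64 follows from it in large part. Only -0.04 compares libraries whose means did not enter the choice. The balance was 40 higher and 253 lower after median-of-ratios scaling and 56 and 221 after quantile normalization. The count was 158 with the smaller pseudocount, 175 with a replicate block, 8 without silicon 1, 59 without silicon 2, 1228 without control 1, 75 without control 2, 178 without control 3, 89 without salt 1, 144 without salt 3, and 60, 122 and 98 without salt plus silicon 1, 2 and 3. The 4 named calls were lost without silicon 1. With 1 library left out, the call for Csa1G423000 was lost in 9 of 11 fits, that for Csa6G486960 in 9 and that for Csa3G646510 in 7, each also without silicon 2. Csa3G646510 and Csa1G423000 lost the call with a replicate block, Csa1G423000 and Csa6G486960 with the smaller pseudocount, and Csa1G423000 without a filter.

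**Figure D3:**
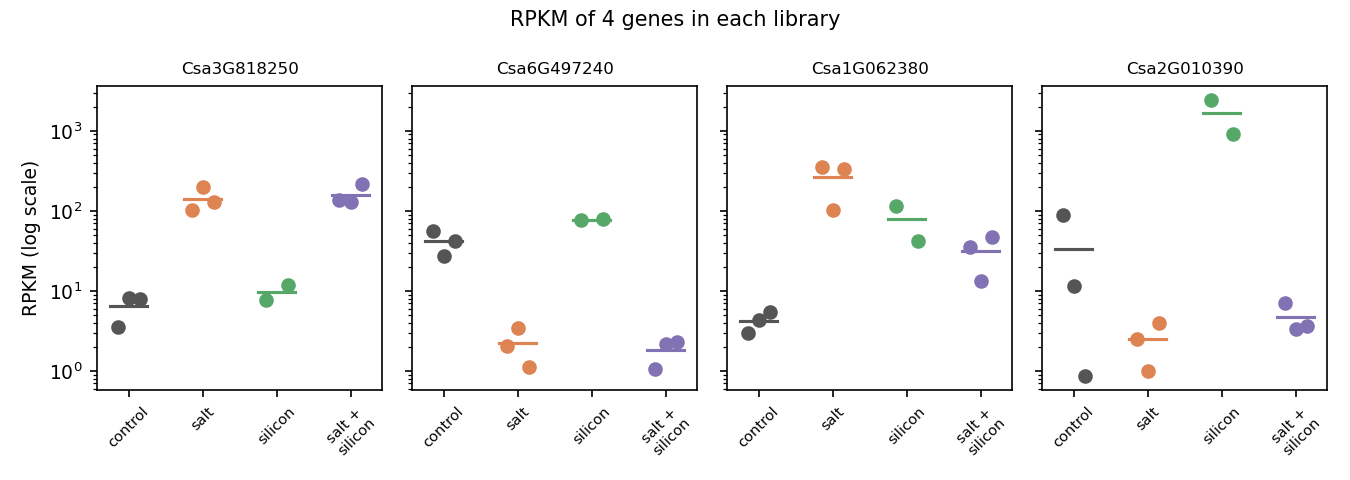
RPKM on a log axis of Csa3G818250, Csa6G497240, Csa1G062380 and Csa2G010390 in each library; points are libraries and lines group means. Csa3G818250 stands at 142 and 160 RPKM in the salt and salt plus silicon groups and at 6.57 in control, while Csa2G010390 reaches 1675 RPKM in the silicon group and 4.70 in salt plus silicon.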

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

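Of the tests here, the interaction was planned, and the tests of splits, scaling, control differences, interval widths and sets of 3 libraries were written down or chosen after the results they bear on had been seen.

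The interaction term of silicon and salt passed the test in 339 genes. The count was 8 without silicon 1 and 1228 without control 1, it lay between 59 and 479 without any other library, and 3 of 100 simulations with no effect gave as many. Among named genes, the interaction on the log2 scale was -6.74 for Csa1G062380, -7.39 for Csa6G486960, 2.44 for Csa1G586900, 2.20 for Csa6G512910, 2.50 for Csa3G646510 and 2.49 for Csa1G423000. Csa1G586900 and Csa6G512910 were named for their fall with silicon alone, which the interaction contains with opposite sign. Their positive values are therefore partly built in, and the others in this list were picked by the interaction itself. For the genes listed at 0 in 3 groups, fitted interactions were 4.97 for Csa1G050120, -7.91 for Csa6G116670 and 3.45 for Csa6G358140, which depend on the pseudocount and are no measure of size.

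With silicon alone, more genes were higher than lower, 94.6% of the 2-fold calls. Scaling of the deposited values is not the whole cause by this test: 79.5% of 2-fold calls were still higher after median-of-ratios scaling. Variation between plants that the controls already show stays open. Across the silicon-higher genes, control 1 minus control 3 correlated with silicon minus control 2 at 0.593. In 6 of 100 simulations with noise drawn anew for each library, the correlation was of that size. That noise was built from the deviations of all libraries within groups, the controls included, so it can carry the same variation. The 6 of 100 is thus no comparison with controls that lack such variation. The set of silicon-higher genes was chosen after seeing its correlation and that over all genes, 0.341. The other choices of reference control gave 0.259 and 0.550 in the silicon-higher genes. With 3 controls and 2 silicon libraries, and counts of 80 without silicon 1 and 2515 without control 1, this and an effect of silicon cannot be told apart.

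In salt-treated plants few genes were called for silicon. On the log2(RPKM + 1) scale, the 95% interval lay within 4-fold for 93.0% of tested genes and within 2-fold for 68.9%. That scale understates changes of low genes. Among the 13969 genes at 5 RPKM or more in at least 2 libraries, the shares were 92.3% and 71.1%. In the simulated data, 55.5% of 4-fold and 14.3% of 2-fold changes were recovered for this comparison. Limited power may therefore hide changes of either size, and whether it accounts for the low count is open. The 6 libraries allow 10 splits, too few for a share under 0.05; 6 of them gave 3 or more calls, the real one included, and the highest other gave 5. For salt against control 1 of 10 splits reached the real 1587, with 6 as the highest other, and for salt plus silicon against control 1 of 10 reached 1102, with 4 as the highest other, again too few splits for a share under 0.05. Splits were not run for silicon against control, salt plus silicon against silicon or the interaction.

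The 3 genes called for silicon in salt-treated plants each had values in 3 libraries and were listed at 0 in the rest. Among all listed genes, 88 had values above 0 in exactly 3 libraries and reached 5 RPKM, which gives 0.533 per set of 3 libraries. The salt plus silicon libraries held 2 such genes. Of the 165 possible sets, 18, this one included, held 2 or more, and the highest held 7. Values that fall on 3 libraries without regard to treatment may therefore account for these 2 calls. The salt libraries held 1 such gene, Csa6G116670. Their set was not ranked by this rule. By a like rule, 5 RPKM or more in all 3 libraries and under 1 RPKM elsewhere, they held 1 gene. By that rule 46 other sets of 3 libraries held as many or more. Values without regard to treatment may therefore account for that call too. Csa6G116670 stands higher than most, since 2 of the 88 genes, itself included, had a smallest value of 156 RPKM or more. No biological explanation was tested.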

How the results depend on the processing

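The alternatives below were planned, except leaving out genes listed at 0, which was chosen after seeing the data. Fitting the compared groups alone gave 196 calls for salt against control, 53 for silicon against control and 475 for salt plus silicon against control. It gave 10 calls for salt plus silicon against salt and 1826 for salt plus silicon against silicon. Counts fell in 3 comparisons and rose in 2, and the cause was not tested. All 3 calls for salt plus silicon against salt were genes listed at 0 in a compared group, so leaving out such genes could only give 0 calls. With these genes kept, limma gave 489 genes an unadjusted p under 0.05, where 870.4 are expected on average with no effect. A pseudocount of 0.1 gave 158 calls for the interaction; the cause was not tested. With 1 library left out, counts ran from 452 to 1922 for salt against control, 80 to 2515 for silicon against control, 3 to 12 for salt plus silicon against salt, 215 to 1408 for salt plus silicon against control, 409 to 1931 for salt plus silicon against silicon and 8 to 1228 for the interaction; a group left with 1 library is assumed to vary like the others. The correlation of salt effects ran from 0.207 to 0.424 and the share of salt-changed genes on the control side from 66.0% to 84.1%.

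The replicate block gave 1031 calls for silicon against control, 727 for salt plus silicon against control and 175 for the interaction, and moved the other counts by less than 1.5 times. The planned fit had no block, and whether replicate numbers pair the samples stays open. Deviations from group means, which depend on each other within a group, were correlated between same-numbered libraries of different groups. These correlations ran from -0.195 to 0.156 (median 0.0591, 5 of 15 above 0.1), against a median of -0.0284 and 4 of 30 above 0.1 for pairs with different numbers, and 5 of 11 libraries correlated best with their own number.

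Named genes gave 433 results over 23 gene and comparison pairs, of which 384 stayed past the threshold, 49 lost the call (38 with 1 library left out) and 0 reversed direction. The planned tests of gene lists, and their repeat with an estimated correlation, were not run because IDs were not paired with names. Absolute depth is unknown, so values of low genes carry no counting error here.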

Other observations

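All tests in this part were chosen after the patterns had been seen.

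With silicon alone, 21 genes were at 5 RPKM or more in both silicon libraries and under 1 RPKM in the other 9. No other pair among the 55 possible pairs of libraries had more than 7 such genes. This is not a like comparison, since silicon is the only group of 2 libraries. Every other pair mixes groups or leaves out a library of its own group, in which such a gene must be under 1 RPKM. The salt plus silicon, salt and control groups had 2, 1 and 0 such genes, where other sets of 3 libraries had up to 6.

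Genes called together tended to follow each other in ID order. With silicon, 214 neighbouring pairs were both higher, 1.75 times the 122 expected when calls were shuffled within expression deciles (permutation p = 1e-04, the smallest that 10000 shuffles can give, Benjamini-Hochberg adjusted 2e-04 over 4 tests). With salt, 101 pairs were both higher against 65.5 expected (permutation p = 1e-04, adjusted 2e-04) and 27 both lower against 15.9 (p = 0.005, adjusted 0.007), while silicon-lower genes gave 1 pair against 1.74 (p = 0.8). A hypothesis is that neighbouring genes vary together also without treatment: their deviations within groups correlated at a mean of 0.145, against 0.0837 for random pairs and 0.091 in the highest of 100 sets of random pairs. Reads shared between neighbours, in libraries without strand, may contribute and were not tested, and that ID order follows the chromosomes was not checked against a genome.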
